A study of Homo sapiens with 12 samples.

How the data were processed

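Spatial gene expression was measured with Visium slides in tumour sections of 6 patients with biliary tract cancer. Each patient gave 1 section taken after pembrolizumab and before GM-CSF (pre) and 1 taken after both drugs together (post), so that 12 libraries formed 2 groups of 6. A Visium slide carries barcoded spots that capture polyadenylated RNA from the tissue above them, and 1 spot can hold RNA of several cells. The labels describe the tissue both as formalin-fixed and as frozen and embedded in OCT. Their protocol is the fresh-frozen capture chemistry, and mitochondrially encoded genes, which that chemistry captures, were present in all 12 libraries. How the tissue was preserved is therefore not settled by the sources used here.

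The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and spot, made with Space Ranger 4.0.1 per the file headers, whereas the submitters' processing notes name Space Ranger 1.3.1, Seurat 4.1.1 and the build GRCh38. The annotation release and the version that made each value are not given in the sources used here, and no coordinates were used. Each matrix held only spots marked as lying under tissue, 7391 in all, and 33538 genes with their symbols and Ensembl identifiers. Nothing in the headers or labels records a normalisation of the counts. For each gene and section the authors also deposited a spatial autocorrelation score, named I in the file headers (Moran's I in Space Ranger's output). Beside it stood a p-value and an adjusted p-value that the authors made within each section, and a normalised average signal per spot that the authors deposited and that was not used here. Spot positions and image scale factors were deposited too. Both sections of pair 6 had been imaged at another scale than the other 10, which was treated as a batch of 1 pair.

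Genes of the Y chromosome and genes of X inactivation, 102 in all, were left out of every test and table, which left 33436 genes. Of these symbols, 24 were duplicated and kept apart by identifier. The genome table given here, of assembly GRCh38.p14, served only for gene names and for the choice of the genes left out. Of the list genes, 1 carried an older symbol in the files (WARS). Genes that share sequence with a close copy (HBA1 and HBA2, SAA1 and SAA2, the HLA genes, the immunoglobulin constant genes, TRBC1 and TRBC2) are uncertain, since reads may have been divided between copies.

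The following choices were made before the data were examined: the groups, tests, filters, 27 gene lists, 16 genes to be reported in any case, and the rule for other named genes. Post against pre, the rule took up to 10 higher and 10 lower genes past the threshold that went the same way in at least 5 pairs, or the 5 genes of smallest p per direction where fewer passed. It also took the 4 tested members of each list with the highest mean CPM. In the contrasts within sections it took up to 12 genes per direction past the threshold, changed the same way in all patients and above the median expression. Spot regions were described by the 6 leading genes by fold among genes found in at least 25% of their spots. Immunoglobulin and T cell receptor segments, HLA-DRB and HLA-DQ genes, GSTM1, GSTT1, UGT2B17 and genes without a symbol were never named. A few genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

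Spots of 1 section are not replicates, so counts were summed per section. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with its default settings, TMM factors, the robust quasi-likelihood F test), with Benjamini-Hochberg adjustment and a threshold of 0.05. Post against pre, the mean CPM of a gene was scaled to the section's total alone, while the number of pairs in which it was higher or lower was counted after TMM scaling. The main design had no patient block, since the labels state no method, although the sections are paired by patient. A fit with the patient as a block was therefore set beside it. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. Camera compares a list's shift with that of all other genes. fry's p tests whether the genes of 1 list move, on balance, one way, and does not compare the list with other genes. List abundance was the list's CPM (UMIs scaled to the section's total), compared as log2(CPM + 10) with a two-sided exact permutation test over the 924 splits of the 12 libraries, and with an exact sign-flip test over the 64 sign patterns of 6 pairs.

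Shares of spots with at least 1 UMI of a list were taken over spots with at least 200 UMIs, each thinned at random to 200 UMIs, in libraries with at least 20 such spots. Co-occurrence of T cell and macrophage UMIs was log2 of (observed + 0.5) over (expected + 0.5) thinned spots holding both, the expected number being the product of both shares. For the contrasts within sections, spots with at least 200 UMIs were called rich in a list when the list's share of UMIs lay above the 75th percentile of the section and above 0, and poor when it lay at or below the median. Rich and poor spots were summed per patient over both sections and compared with edgeR with the patient as a block, and genes of the list that defined the spots were left out. The change of these contrasts from pre to post was the interaction of region and time over sums per section. Spot regions came from Leiden clustering (leidenalg 0.10.2) of 4980 spots on log-normalised values scaled to 10000 UMIs. It used 2000 variable genes, 20 principal components, 15 neighbours and resolution 0.5, without integration of libraries. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

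The procedures were tested on simulated data with the real genes, means and library sizes and 100 genes each changed 2-fold and 4-fold. Post against pre, over 6119 genes, the test without the patient block recovered 0% of the 2-fold and 26% of the 4-fold changes, and with the block 24% and 98%. In the epithelial contrast (4130 genes) it recovered 59% and 100%, and in the macrophage contrast (4680 genes) 67% and 99%. Simulated genes varied independently of each other and carried the same fold in every patient. These shares may therefore be too high for the real sections, where changes can differ between patients.

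The same patient numbers stand in the labels of both groups, and same-numbered sections come from the same patient per the labels. Their deviations from the group means correlated at 0.299, 0.783, 0.464, 0.591, 0.717 and 0.652 for pairs 1 to 6, and in 5 of 6 pairs the own partner correlated best, so the numbers were taken to pair the sections. No pair of libraries was alike within sampling noise (lowest chi-square per degree of freedom 2.37), so none was taken for a repeat deposit. With 6 patients, p-values of single genes and of the exact tests measure the spread between patients' sections. Each section samples a small part of a tumour. Camera's p at the preset correlation treats genes as nearly independent and rests on the spread between genes, not between patients. With the patient as a block, its adjusted p for the fibroblast and matrix list was 1.41e-13. The adjusted p was 0.40 with an estimated correlation (0.81) and 0.664 by fry.

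Total UMIs per section ranged from 36805 to 2261506, and a count of 0 in a section allowed a level of up to 1.33 CPM in the deepest and 81.5 CPM in the shallowest (3 counts, for counting error only). Alternatives tried were the patient block, DESeq2 1.42.0, voom with quality weights, no TMM factors, other filters on low counts and on spots, no hepatocyte-rich spots, list levels as covariates, no library under 50000 UMIs, other pseudocounts and denominators, other thinning depths, a split of spots at the median, 1 time point only, and leaving out each library or patient. Alternatives without pair 6, and the blocked alternatives without a pair, with another tool or with a covariate, were added after the data had been seen.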

Results

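Sections of biliary tract cancer from 6 patients were profiled at 2 times: after the PD-1 antibody pembrolizumab (pre) and after GM-CSF, a growth factor of myeloid cells, had been given together with it (post). The labels name the trial of this combination, and the design asks what differed in the tissue after GM-CSF was added. No section from before pembrolizumab was analysed here. Every post section was taken later than its pre section, and no later section without GM-CSF was analysed. The passage of time and continued pembrolizumab therefore cannot be told apart from GM-CSF. The labels do not give the biopsy site of a section, and hepatocyte genes differed within pairs (46015 CPM pre and 131850 CPM post in pair 3, 14091 and 4152 CPM in pair 6), so differences of treatment and of sampled tissue are mixed in every comparison of post with pre. The 12 libraries held 7593024 UMIs over 7391 tissue spots. Totals for pairs 1 to 6 were 194442, 569250, 369598, 75904, 675462 and 373636 UMIs pre and 36805, 404299, 1556538, 558709, 2261506 and 516875 UMIs post. They covered 431, 453, 536, 143, 694 and 1274 spots pre and 145, 245, 1040, 996, 886 and 548 spots post. The median section had 267.5 UMIs per spot pre and 599 post, a difference within the spread between sections (exact permutation p = 0.195, two-sided). Between 5644 and 16208 genes were detected per section. Mitochondrially encoded genes took 48.8% of UMIs in the post section of pair 1, the shallowest library, and 6.96% to 15.4% in the other 11.

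**Figure D1:**
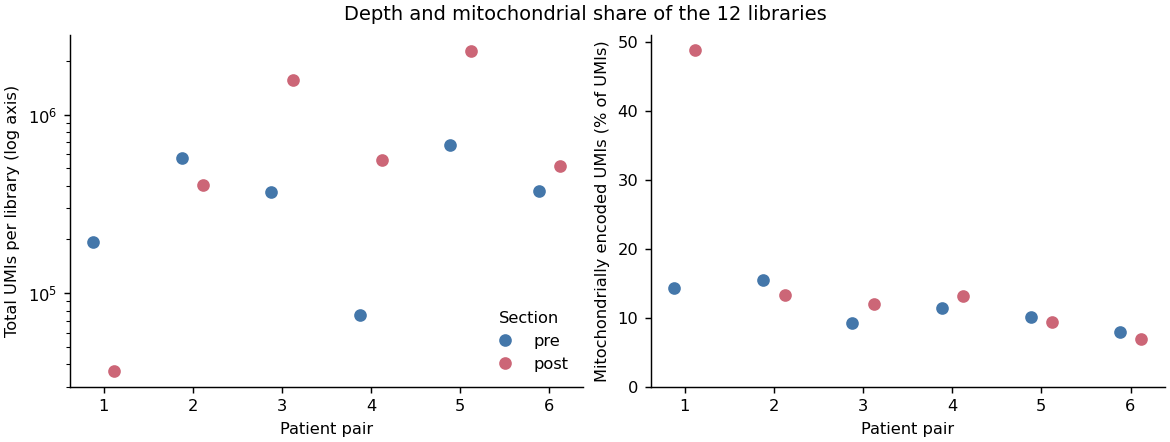
Total UMIs per section on a log axis and percent of UMIs from mitochondrially encoded genes, for the pre and post sections of each of 6 pairs; points are single sections. Totals lie between 36805 and 2261506, and the post section of pair 1 stands apart at 48.8% mitochondrial UMIs.

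Post against pre, no single gene passed adjustment. The neutrophil calgranulin S100A9 stood at 88.5 ± 106 CPM pre and 245 ± 208 CPM post (SD, n = 6 each; log2 fold change 1.45 ± 0.835 SE, higher in 4 of 6 pairs), and its partner S100A8 had a log2 fold change of 1.40 ± 0.895. KRT19, a keratin of bile duct epithelium, measured 478 CPM pre and 641 CPM post (0.49 ± 0.830, higher in 5 pairs), and the epithelial adhesion protein EPCAM 195 and 198 CPM (0.10 ± 0.721). The macrophage scavenger receptor CD163 (0.64 ± 0.835), the lysosomal macrophage marker CD68 (0.11 ± 0.490) and the antigen-presenting HLA-DRA (0.06 ± 0.789) were likewise within error. ALB, the albumin of hepatocytes, gave −0.60 ± 2.08. The smallest p values among higher genes belonged to EMC6, a subunit of a membrane protein insertion complex (22.4 ± 14.3 to 49.2 ± 21.7 CPM, 0.89 ± 0.354, 6 of 6 pairs), DVL1, a Wnt signal transducer (0.76 ± 0.312, 6 pairs), PRPS2 (0.89 ± 0.374), the cytochrome oxidase assembly factor COX11 (0.95 ± 0.413) and the complex I assembly factor TMEM126B (0.81 ± 0.358). Among lower genes they belonged to the tubulin folding cofactor TBCC (32.8 ± 12.4 to 13.7 ± 9.01 CPM, −1.01 ± 0.314, lower in 6 of 6 pairs), PPME1 (−0.95 ± 0.306), the hyaluronan-degrading CEMIP (−1.57 ± 0.545, lower in 6 pairs), the phosphatase PTP4A3 (−1.46 ± 0.519) and the ciliary IFT122 (−0.96 ± 0.344), all with adjusted p = 1.0.

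Of 6119 genes tested with edgeR, 0 passed and 20 had an unadjusted p under 0.05. With the patient as a block 0 passed and 149 had such a p, with DESeq2 0 and 37, and with voom and quality weights 0 and 134. Blocked log2 fold changes were 1.75 ± 0.723 SE for S100A9, 1.33 ± 1.03 for S100A8, 0.63 ± 0.350 for KRT19 and 0.36 ± 0.318 for EPCAM. In the same fit CD163 gave 0.46 ± 0.390, CD68 0.12 ± 0.280, HLA-DRA −0.28 ± 0.310 and ALB −0.21 ± 0.573. The blocked test called 8 genes, all lower post, only when pair 5 was left out, chiefly collagen and matrix genes such as COL3A1 (−2.06 ± 0.385, adjusted p = 0.0328). In simulated data the unblocked test recovered 26% of 4-fold and 0% of 2-fold changes, and the blocked test 98% and 24%. Those data held independent genes with the same fold in every patient, so real changes may be found less often.

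Most genes of the drugs' own targets were too sparse to test. CSF2RA and CSF2RB, which form the GM-CSF receptor, had 13 and 21 UMIs over all pre sections and 31 and 29 over all post sections. CD274, which encodes PD-L1, had 9 and 28 UMIs, PDCD1, its receptor PD-1, 5 and 13, the cytotoxic T cell coreceptor CD8A 25 and 75, and the dendritic cell marker CD1C 6 and 25. The interferon-induced chemokine CXCL9 had 111 and 259. The post sections held more UMIs in all, so these sums do not compare the groups and no fold is given.

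Genes of fibroblasts and extracellular matrix lay lower post. Of the 18 tested members 17 had a negative log2 fold change (median −0.84, range −1.08 to 0.30), and the list fell relative to all other genes (camera adjusted p = 1.65e-07, but adjusted p = 0.759 with an estimated correlation). COL1A1, a chain of type I collagen, measured 5435 ± 6721 CPM pre and 2488 ± 3909 CPM post (−1.03 ± 1.04, lower in 5 of 6 pairs). COL1A2 gave −0.86 ± 1.03, COL3A1 −0.97 ± 1.09 and the matrix glycoprotein SPARC −0.60 ± 0.904. With the patient as a block all 18 members were lower (median −1.16, adjusted p = 1.41e-13, and adjusted p = 0.403 with an estimated correlation). Endothelial genes were also lower in all 7 tested members (median −0.36, adjusted p = 0.00698; 0.759 as the adjusted p with an estimated correlation), among them EGFL7 (92.8 to 48.7 CPM, −0.90 ± 0.455), the TGF-β coreceptor ENG (−0.41 ± 0.553), VWF (−0.32) and PECAM1 (−0.36). Epithelial genes were higher in 15 of 18 members (median 0.28, adjusted p = 1.38e-04, and adjusted p = 0.759 with an estimated correlation), including KRT19 and KRT8 (0.17), while KRT18 (−0.12) and CEACAM6 (−0.25) were on the other side. No member of these lists passed singly without the patient block, whether over all genes or adjusted over the list alone. With the block 1 endothelial gene, the tight junction claudin CLDN5 (56.1 to 13.7 CPM, −1.88 ± 0.408, lower in 5 of 6 pairs), passed adjusted over the list alone but not over all genes (adjusted p = 0.562). Without the pre section of pair 5 the epithelial call was lost (adjusted p = 0.493), and without the post section of pair 6 the fibroblast call (0.0719). The endothelial call was lost without the pre section of pair 3 (0.124) or 5 (0.325), or the post section of pair 1 (0.0510), 2 (0.668) or 6 (0.0719).

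The 13 mitochondrially encoded genes, a sign of RNA quality, were all higher post (median 0.57, camera adjusted p = 0.00184, and adjusted p = 0.759 with an estimated correlation). MT-ND4, a complex I subunit, went from 18338 to 29470 CPM (0.75 ± 0.533) and was higher in 3 of 6 pairs after TMM scaling and in 4 by plain CPM. MT-CO3 gave 0.74, and MT-ATP6 and MT-ND3 0.60 each. The shift rested on few libraries: without the post section of pair 1 the list pointed down (adjusted p = 0.737), and the call was lost without the pre section of pair 3 (0.117) or 6 (0.0769) and without hepatocyte-rich spots (0.0753). Immediate early and stress genes, also a sign of tissue handling, had a median of −0.45 with 7 of 9 lower (adjusted p = 0.177). With the patient as a block this list was called (7 of 9 lower, median −0.34, adjusted p = 0.0367, and adjusted p = 0.653 with an estimated correlation), and 1 member passed adjusted over the list alone. FOS gave −2.30 ± 1.21 although 4 of 6 pairs were higher, JUNB −0.71, DUSP1 −0.37 and HSPA1A 0.34.

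The other 10 lists that could be tested did not pass. GM-CSF signalling had 4 of 5 tested members lower (median −0.44, adjusted p = 0.449), with the monocyte chemoattractant CCL2 at −0.81 ± 0.503, the feedback inhibitor SOCS3 at −0.60, the survival gene BCL2L1 at −0.44 and STAT5B at −0.08. With the patient as a block all 5 were lower (median −0.34, camera adjusted p = 0.0670, and adjusted p = 0.561 with an estimated correlation). Macrophage genes were split 9 higher to 6 lower (median 0.11, adjusted p = 0.951), with the complement genes C1QA at −0.02 and C1QB at 0.65, the lysozyme LYZ at 0.18 and the endotoxin coreceptor CD14 at −0.09. MHC class II genes had a median of 0.08 with 6 of 8 higher (adjusted p = 0.635), CD74 at 0.10, HLA-DPA1 at −0.16 and HLA-DPB1 at 0.14. MHC class I genes had a median of −0.00 while camera's direction was up (adjusted p = 0.951), with B2M at −0.06, HLA-B at 0.12 and HLA-C at −0.28. Interferon gamma response genes (median 0.12, 4 of 7 higher, adjusted p = 0.951) included UBD at 0.70, IRF1 at −0.17 and WARS at 0.13. For type I interferon genes (5 of 10 higher, adjusted p = 0.951) the median was 0.04 and camera pointed down, with IFI27 at 0.52, ISG15 at 0.23, IFI6 at −0.31 and MX1 at −0.50. Hepatocyte genes were lower in all 15 tested members (median −0.35), yet camera's direction was up (adjusted p = 0.951). Hypoxia and glycolysis genes were lower in all 11 (median −0.20, adjusted p = 0.449), with LDHA at −0.42, PGK1 at −0.28, ENO1 at −0.03 and NDRG1 at −0.01. Acute phase genes (median −0.13, 3 of 8 higher, adjusted p = 0.951) included CRP at −0.88, SAA2 at −0.58, C3 at −0.23 and SAA1 at 0.05. Ribosomal protein genes had a median of −0.06 with 8 of 31 higher (adjusted p = 0.449), with RPL13 at −0.27, RPL10 at −0.24, RPLP1 at −0.05 and RPS27 at 0.05. No member of these lists passed adjusted over the list alone, with or without the patient block, and fry's adjusted p was 0.992 for all 15 lists. The median log2 fold change of all genes was −0.05.

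**Figure D2:**
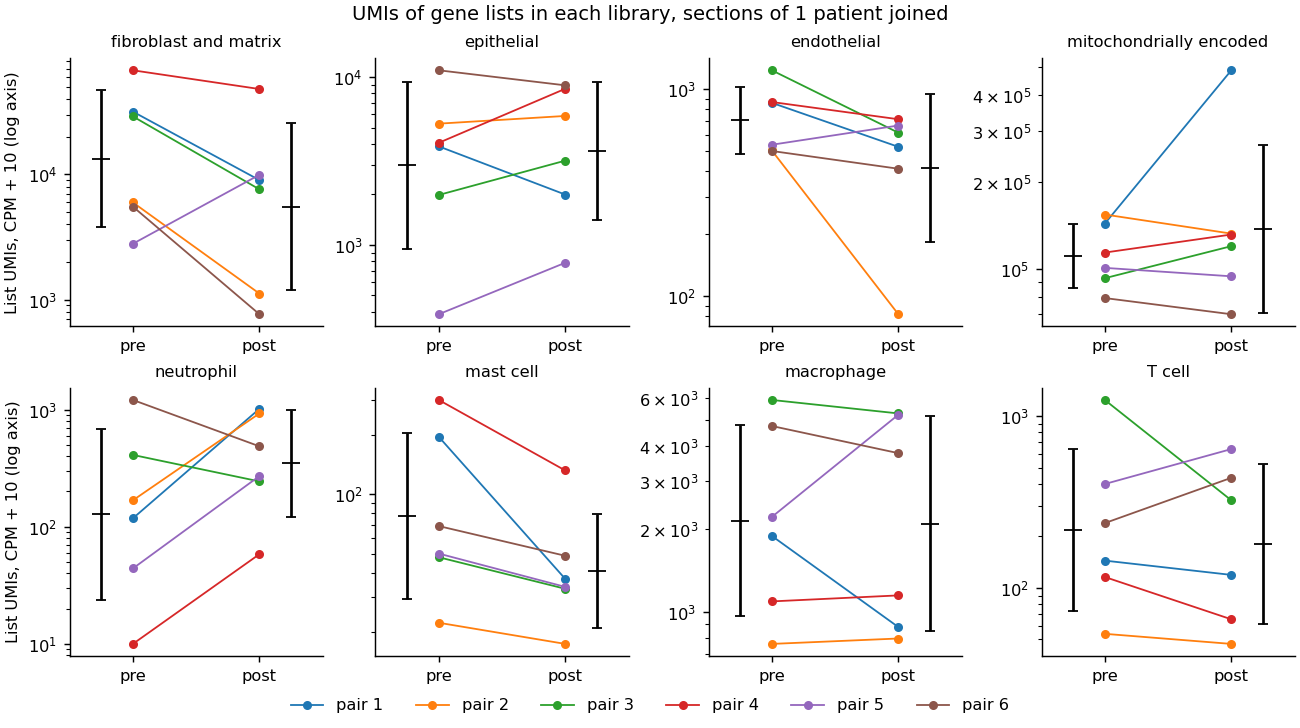
Summed CPM of 8 gene lists, with 10 CPM added, on a log axis in pre and post sections; lines join the 2 sections of a patient and black marks are the mean and SD on the log2 scale (n = 6). The fibroblast and matrix list was lower post in 5 of 6 pairs and the macrophage list shows no common direction.

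As shares of all UMIs, no list passed adjustment. The fibroblast and matrix list took 23832 ± 25034 CPM pre and 12746 ± 17772 CPM post (SD, n = 6 each), a 0.411-fold geometric mean ratio with 5 of 6 pairs lower (exact permutation p = 0.286). The endothelial list took 741 ± 291 and 493 ± 233 CPM (0.589-fold, 5 of 6 lower, exact permutation p = 0.160), GM-CSF signalling 450 ± 192 and 311 ± 90.8 CPM (0.724-fold, 4 of 6 lower, exact permutation p = 0.147, the lowest of all lists). Neutrophil genes took 317 ± 455 and 490 ± 390 CPM (2.72-fold, 4 of 6 higher, exact permutation p = 0.247; log2 0.71 without the pre section of pair 4, which held 0 CPM) and mast cell genes, 310 UMIs in all, 104 ± 110 and 40.3 ± 41.1 CPM (0.528-fold, 6 of 6 lower, exact permutation p = 0.223, exact sign-flip p = 0.0312). The macrophage list stayed at 2754 and 2836 CPM (log2 −0.04) and the epithelial list went from 4411 to 4864 CPM (1.21-fold). None of the 27 lists passed: the adjusted permutation p was 0.981 for each, the adjusted sign-flip p at least 0.844, and 0 lists had an unadjusted permutation p under 0.05. Neither test could have called 1 list alone: the smallest p that 924 splits or 64 sign patterns allow does not pass over 27 lists. The adjusted values therefore do not show that list shares stayed unchanged.

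The remaining lists with under 5 tested members were compared by this share alone. T cell genes took 355 CPM pre and 262 CPM post (log2 −0.28) and cytotoxic lymphocyte genes 124 and 140 CPM (−0.02). Of their most abundant members, the T cell receptor constant genes TRBC2, TRAC and TRBC1 gave log2 fold changes of −0.58, 0.02 and −0.01, the coreceptor CD4 0.06, the chemokine CCL5 0.12 and the granule protein NKG7 −0.13. B and plasma cell genes took 4065 and 4367 CPM (0.28), with the immunoglobulin genes IGKC at 0.24, IGHA1 at −0.06 and IGHG1 at −0.53 and the joining chain JCHAIN at −0.64. Dendritic cell genes took 184 and 146 CPM (−0.17), among which the lymphoid chemokine CCL19 was lower post in 5 of 6 pairs and higher in none (−0.90 ± 1.29). Checkpoint and regulatory T cell genes took 132 and 127 CPM (−0.06), with VSIR at 0.14 and ENTPD1 at 0.38, and proliferation genes 351 and 363 CPM (−0.08), with STMN1 at 0.17, PCNA at 0.47 and MCM3 at 0.11. The neutrophil chemoattractant CXCL8 (137 ± 278 CPM pre, 65.2 ± 56.5 post) gave −1.03 ± 1.13 although it was higher post in 5 of 6 pairs, and 0.28 with the patient as a block. Erythrocyte genes took 1241 and 8214 CPM (1.14), with the haemoglobin genes HBA2 at 3.27 ± 1.61, HBA1 at 3.05 and HBB at 1.98. The post section of pair 1 held 33936 CPM of them, and without it the share differed by 0.08. With the patient as a block the 3 genes gave 0.84, 0.78 and 0.81. Eosinophil (4.94 and 9.67 CPM), lung alveolar (6.21 and 7.93 CPM) and adipocyte (23.8 and 17.0 CPM) genes were rare, with 51, 49 and 175 UMIs over all sections.

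Shares of spots were compared after thinning to 200 UMIs. Unthinned shares were taken over all tissue spots, those under 200 UMIs included, so they differ in the spots covered as well as in depth. Spots with a macrophage UMI made up 38.1% ± 22 pre and 36.9% ± 23.3 post (SD, n = 6 each, exact permutation p = 0.935), against 45.0% and 56.9% unthinned. Spots with a T cell UMI made up 6.99% ± 7.55 and 4.24% ± 4.53 (exact permutation p = 0.524), against 12.5% and 19.4% unthinned. Endothelial spots went from 14.3% ± 5.13 to 9.35% ± 3.46 (exact permutation p = 0.0801, adjusted p = 0.687; unthinned 22.5% and 26.8%) and mast cell spots from 2.32% ± 2.04 to 0.967% ± 1.16, lower in 6 of 6 pairs (exact sign-flip p = 0.0312, adjusted p = 0.469). Mast cell spots were few. Pair 2 had 2 of 402 pre and 1 of 227 post, and pair 5 had 2 of 319 and 5 of 824, nearly equal shares. The post section of pair 1 had 0 of 44. Neutrophil spots made up 6.0% and 9.50% (unthinned 10.2% and 28.6%), cytotoxic lymphocyte spots 1.99% and 2.62%, and B and plasma cell spots 25.7% and 36.0%. The B and plasma cell difference of 10.4 points moved with single sections. It was 3.78 without pair 6, whose post section stood at 86.8%, and 18.1 without the pre section of pair 3. Epithelial spots stood at 39.99% and 44.04%, hepatocyte spots at 62.1% and 62.0%, fibroblast spots at 71.5% and 56.3%, dendritic cell spots at 3.46% and 2.51%, and erythrocyte spots at 12.0% and 30.1%. Eosinophil (0.0649% and 0.180%), lung alveolar (0.144% and 0.0507%) and adipocyte spots (0.577% and 0.317%) were rare. None of the 15 cell type lists passed, and 0 had an unadjusted exact permutation p under 0.05. The sign-flip test could not have called 1 list alone here, since 0.0312 is the smallest p that 6 pairs allow.

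Spots shared by T cell and macrophage UMIs were compared with the number set by their separate shares. Averaged over sections, each counted alike, this ratio was lower post than pre, but sections with few expected spots may carry the difference. The T cell list includes CD4, which macrophages also express, so macrophages alone can make a spot count as shared. The log2 ratio of observed to expected shared spots was 0.75 ± 0.575 pre and −0.11 ± 0.573 post (SD, n = 6 each), a difference of −0.87 (exact permutation p = 0.0108, two-sided). The ratio was lower post in 5 of 6 pairs, and with the patient as a block the difference of −0.87 no longer passed (exact sign-flip p = 0.0625). The post section of pair 1 had 0 spots with T cell UMIs, which fixes its ratio at 0. Without that section the difference was −0.89 (exact permutation p = 0.0260), and without pair 1 it was −0.90 within pairs (exact sign-flip p = 0.125). Over all sections 220 thinned spots held both kinds of UMI against 184.5 expected, and most sections held few: 4 against 2.21, 3 against 0.940, 55 against 53.6, 2 against 0.350, 13 against 8.35 and 23 against 18.4 in pre sections 1 to 6, and 0 against 0, 0 against 0.670, 27 against 21.8, 1 against 1.01, 76 against 60.04 and 16 against 17.1 in post sections 1 to 6. Over the 3 pre and 3 post sections with at least 5 expected spots, the ratios were 0.32 and 0.18, a difference of −0.14 (exact permutation p = 0.5, where 0.1 is the smallest possible).

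**Figure D3:**
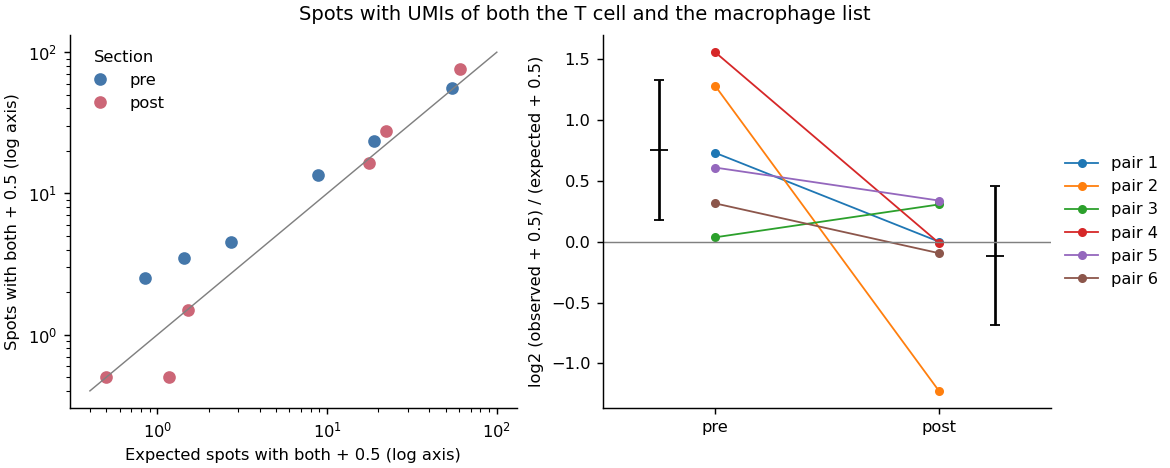
Left, observed against expected numbers of thinned spots with both T cell and macrophage UMIs per section, with 0.5 added, on log axes; right, the log2 ratio of each section by pair, with group mean and SD (n = 6). The mean ratio was 0.75 pre and −0.11 post, and the sections farthest from the diagonal have few expected spots.

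Within sections, spots rich in epithelial RNA were set against spots poor in it, to describe what went with epithelial RNA. No label or list here tells tumour from normal epithelium. In pair 5 spots counted as rich above 0.0509% of UMIs pre and 0.100% post. Stromal genes lay lower in epithelial-rich spots in almost every patient: the small proteoglycan DCN measured 2200 CPM in poor and 684 CPM in rich spots (log2 −1.66 ± 0.259 SE), COL1A1 6769 and 2268 CPM (−1.23 ± 0.232), COL3A1 −1.27 and the complement component C7 −2.19 ± 0.441, each at adjusted p = 0.0822. In 6 of 6 patients rich spots held more of the progenitor marker PROM1 (46.4 to 219 CPM, 2.17 ± 0.386, adjusted p = 0.0822), PDZK1IP1 (2.34 ± 0.502, adjusted p = 0.0852), the laminin receptor ITGA3 (2.04 ± 0.462, adjusted p = 0.0986) and the receptor tyrosine kinase ERBB2 (1.54 ± 0.371, adjusted p = 0.111). None of these genes passed, nor did the macrophage receptor CD163 at −1.63 ± 0.360 (131 to 39.6 CPM, lower in 6 of 6 patients, adjusted p = 0.0900), HLA-DRA (−1.17 ± 0.324, adjusted p = 0.131), CD68 (−0.69) or IGHA1 (−1.83 ± 0.375, adjusted p = 0.0822). The genes of this contrast, fixed genes and list members aside, were chosen after their values had been seen.

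By list, 8 of 12 passed camera in the epithelial contrast. Fibroblast and matrix genes were lower in all 18 members (median −1.25, adjusted p = 1.07e-17), as were macrophage genes in all 15 (median −1.10, adjusted p = 1.60e-08), hepatocyte genes in all 15 (median −1.15, adjusted p = 1.37e-09), MHC class II genes in all 8 (median −0.70, adjusted p = 0.00150) and endothelial genes in all 5 (median −1.13, adjusted p = 0.00423). Acute phase genes were lower in 6 of 7 (median −0.99, adjusted p = 2.81e-04) and ribosomal protein genes in 29 of 31 (median −0.19, adjusted p = 1.63e-04). Hypoxia and glycolysis genes were higher in 7 of 9 (median 0.42, adjusted p = 0.00488), with the glycolytic enzyme ENO1 at 0.44 and PGK1 at 0.42. None held with an estimated correlation, where the adjusted p was 0.293 for fibroblast, macrophage, hepatocyte, MHC class II, acute phase and hypoxia genes and 0.327 for endothelial and ribosomal ones. Adjusted over the list alone, 17 fibroblast, 13 macrophage, 4 MHC class II, 3 endothelial and 3 acute phase genes passed, and 0 of the hepatocyte, hypoxia and ribosomal lists. Interferon gamma (median −0.07 with camera's direction up, adjusted p = 0.513), MHC class I (0.452), immediate early (0.806) and mitochondrial genes (0.513) did not pass. In spots thinned to 200 UMIs, where 6 lists could be tested, fibroblast and hepatocyte genes kept their call (adjusted p = 1.59e-12 and 0.0415), macrophage and ribosomal genes lost it (0.123 and 0.346), and mitochondrial genes were called higher (0.0166). Over single genes 0 of 4130 passed in edgeR (lowest adjusted p 0.0822), 595 had an unadjusted p under 0.05 (224 higher, 371 lower), and DESeq2 called 119 (40 higher, 79 lower). Without pair 5 edgeR called 56 genes and without pair 6 it called 3.

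Spots rich in macrophage RNA held more RNA of antigen presentation than poor ones, though no gene passed without pair 1, 2, 3 or 4: HLA-DRA measured 1462 CPM in poor and 3424 CPM in rich spots (log2 1.49 ± 0.221 SE, adjusted p = 0.00876), its invariant chain CD74 1614 and 3876 CPM (1.42 ± 0.220, adjusted p = 0.00876) and HLA-DPA1 348 and 832 CPM (1.27 ± 0.231, adjusted p = 0.0299), each higher in 6 of 6 patients. In pair 6 the difference was small (HLA-DRA 0.29, RNASE1 0.02, GPNMB 0.08). Other single genes were higher as well, but no myeloid list was tested in this contrast. Among genes the rule names, the largest differences were in the Fc receptor FCGR2A (54.6 ± 28.5 to 181 ± 71.2 CPM, SD, 1.70 ± 0.257), the complement factor CFD (1.63 ± 0.250), the secreted ribonuclease RNASE1 (1.58 ± 0.343) and GPNMB, a glycoprotein of lipid-laden macrophages (304 to 894 CPM, 1.51 ± 0.293). The osteoclast and macrophage phosphatase ACP5 (1.40 ± 0.308), the carboxypeptidase CPVL (1.39 ± 0.240), the protease CTSS (1.22 ± 0.260) and the granule proteoglycan SRGN (1.22 ± 0.261) followed, with adjusted p between 0.0211 and 0.0446. No T cell or B and plasma cell list was tested in this contrast, but genes that passed included the T cell receptor constant gene TRBC2 (62.4 to 154 CPM, 1.20 ± 0.254, adjusted p = 0.0439), CD4, which macrophages also express (1.45 ± 0.311, adjusted p = 0.0446), and the immunoglobulin light chain IGKC (3827 to 6508 CPM, 0.95 ± 0.191, adjusted p = 0.0424). S100A9 (0.97 ± 0.222, adjusted p = 0.0568, 6 of 6 patients) and CXCL9 (1.95 ± 0.445, adjusted p = 0.0609, 4 of 6) did not pass, nor did S100A8 (0.90), COL1A1 (0.60), TRAC (1.06, adjusted p = 0.130), KRT19 (−0.73), EPCAM (−0.58) and ALB (−0.52). The single lower gene was the glutamate transporter SLC1A1 (−1.27 ± 0.270, adjusted p = 0.0439, lower in 5 of 6 patients), which falls outside the rule and was chosen after its value was seen.

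**Figure D4:**
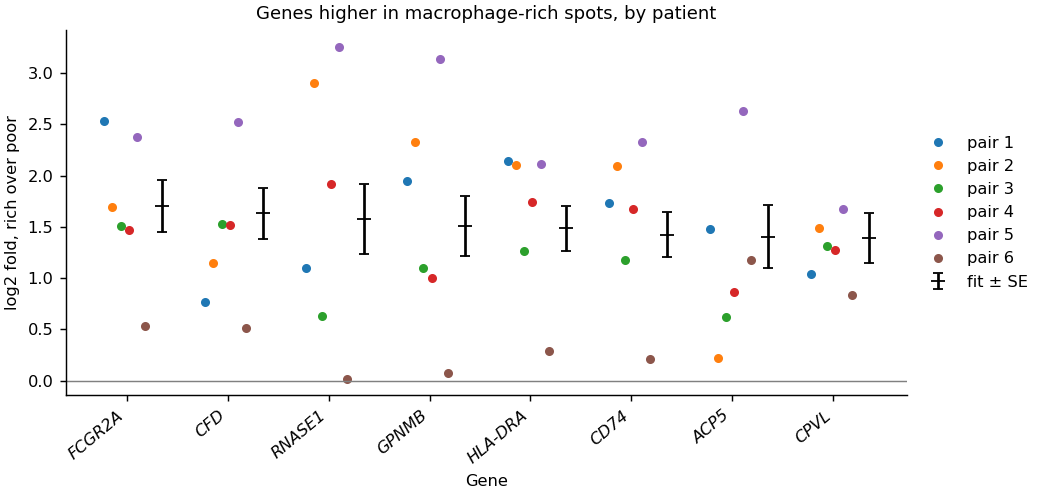
Log2 ratio of macrophage-rich to macrophage-poor spots for the 8 genes with the largest difference among those the rule names; each dot is 1 patient (n = 6) and black marks are the edgeR estimate with its SE. FCGR2A is highest at 1.70 ± 0.257, and CPVL is lowest of the 8 at 1.39 ± 0.240.

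Across lists, 11 of 13 passed camera in this contrast. All 8 MHC class II genes were higher (median 1.37, adjusted p = 1.39e-15), as were all 18 fibroblast and matrix genes (median 0.61, adjusted p = 8.63e-10), all 6 endothelial genes (0.64, adjusted p = 2.68e-04), all 8 type I interferon genes (0.68, adjusted p = 1.35e-04), all 11 MHC class I genes (0.42, adjusted p = 3.45e-07), 7 of 8 interferon gamma genes (0.46, adjusted p = 0.00123) and 30 of 31 ribosomal genes (0.11, adjusted p = 3.69e-05). Lower were all 17 epithelial genes (−0.63, adjusted p = 4.03e-07), all 16 hepatocyte genes (−0.60, adjusted p = 5.03e-08), all 13 mitochondrial genes (−0.42, adjusted p = 4.59e-08) and 6 of 7 acute phase genes (−0.61, adjusted p = 8.68e-04). With an estimated correlation none passed: the adjusted p was 0.110 for MHC class II, fibroblast and type I interferon genes, 0.177 for epithelial, endothelial and MHC class I genes, 0.246 for interferon gamma and mitochondrial genes, and 0.250 for the rest. By fry the MHC class II genes passed (adjusted p = 0.0434) and other lists did not (adjusted p at least 0.0600). Adjusted over the list alone, 12 fibroblast, 8 MHC class II, 4 epithelial, 3 MHC class I, 2 endothelial, 1 interferon gamma and 1 acute phase gene passed. Hypoxia (median −0.25, adjusted p = 0.147) and immediate early genes (−0.18, adjusted p = 0.336) were not called. In thinned spots, where 6 lists could be tested, ribosomal genes lost their call (adjusted p = 0.0883), and epithelial, hepatocyte, fibroblast, MHC class I and mitochondrial genes kept theirs (adjusted p = 0.00740, 0.00983, 0.010015, 9.02e-04 and 1.42e-08).

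In all, 38 of 4680 genes passed in the macrophage contrast, 37 higher and 1 lower in rich spots, and 31 went the same way in 6 of 6 patients. DESeq2 called 57 genes, 37 of them shared. The count depended on which pair was left out: edgeR called 0 genes without pair 1, 2, 3 or 4 (603, 473, 370 and 641 at an unadjusted p under 0.05), 20 without pair 5 and 45 without pair 6. Without the patient block edgeR called 0 genes, with 2.16% of the 4680 at an unadjusted p under 0.05. After thinning each spot to 200 UMIs, which left 630 genes to test, CD74 and HLA-DRA passed, both at adjusted p = 0.0323.

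Neither contrast differed detectably between pre and post. For the epithelial contrast 0 of 2130 genes passed (90 at an unadjusted p under 0.05), the lowest adjusted p being 0.378 for ANXA1, an annexin of epithelium and myeloid cells, whose contrast was 1.87 ± 0.411 larger post. DESeq2 called 1 gene, with 125 at an unadjusted p under 0.05, and without the post section of pair 4 edgeR called 4. For the macrophage contrast 0 of 1343 genes passed (22 at an unadjusted p under 0.05, lowest adjusted p 0.9995), and DESeq2 called 0 with 32. Across genes, which are not independent replicates, the pre and post log2 ratios correlated at 0.519 for the epithelial and 0.641 for the macrophage contrast. ANXA1 was chosen after its value was seen.

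Clustering of 4980 spots gave 13 regions, most of which lay in 1 patient or 1 section. The pre and post sections of pairs 3 and 6 differed: region 4 held 97.3% of the post and 1.75% of the pre section of pair 6, whose pre section lay 69.8% in region 8, and region 7 held 72.5% of the pre and 11.3% of the post section of pair 3. Region 1, led by the matrix genes MATN3, SFRP4, SFRP2, APOD, IGFBP5 and HTRA3, held 744 spots, of which 99.3% came from pair 4. Region 2 (ALB, HRG, TTR, ADH1A, ADH1B, F12) held hepatocyte genes and 633 spots, 93.2% from pair 5. Liver genes also led region 6 (SAA2, SAA1, SLC13A5, APOA1, ATF5, ITIH3; 409 spots) and region 11 (APOA4, ORM1, CYP3A4, LEAP2, LBP, SAA1; 197 spots). Region 3 (HBB, CA9, MTCL1, HBA1, SUCNR1, HBA2; 545 spots) joined haemoglobin genes with the hypoxia-induced carbonic anhydrase CA9 and lay 98.7% in pair 2. Epithelial genes led region 4 (PI3, MUC13, CXCL5, TSPAN8, MMP7, UBD; 541 spots), region 8 (TFF1, AKR1C2, CEACAM6, SPP1, IGLC2, CTSC; 377 spots), region 9 (OLFM4, KRT20, CST1, TFF3, MUC5B, CST4; 249 spots) and region 12 (TFF1, RAB27B, AKR1C2, CXCL8, UCA1, CEACAM6; 131 spots). Region 5 (MMP11, COMP, COL10A1, AQP1, HBA2, ANTXR1, 415 spots), led by genes of activated fibroblasts, was the most widely shared, with spots in 10 libraries of 6 patients. Its share per section averaged 20.04% ± 39.07 pre and 17.04% ± 36.35 post (SD, n = 6 each), and 59.8% of its spots came from pair 1. It held 98.1% of the pre and 90.9% of the post section of pair 1. Region 7 (FOS, JCHAIN, IGHG1, IGHA1, PTGDS, SOD3; 379 spots) carried plasma cell genes, region 10 (CXCL9, LILRB4, CD52, RNASE1, MSR1, GM2A; 232 spots) chemokine and myeloid genes, and region 13 (DES, ACTG2, MYH11, CNN1, FHL1, LMOD1; 128 spots) smooth muscle genes. Of the 6 regions with spots in at least 4 patients, 0 differed in share between post and pre (exact permutation p between 0.576 and 1, adjusted p = 1), and 0 had an unadjusted p under 0.05. Of those 6, regions 1, 3, 7, 8 and 10 held 99.3%, 98.7%, 91.6%, 99.2% and 89.7% of their spots in 1 patient. With shares near 0 in most sections this test could hardly find a difference, so it does not show that regions stayed unchanged. Neighbouring spots fell in the same region in 60.1% to 99.1% of pairs per section, against 20.5% to 98.2% on average when regions were shuffled among spots. The share did not exceed the highest of 200 shuffles in the pre sections of pairs 1 and 4 (97.6% and 98.7%) and the post sections of pairs 1, 2, 4 and 6 (91.3%, 97.9%, 99.1% and 94.5%), where shuffled regions gave 82.3% to 98.2% on average.

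**Figure D5:**
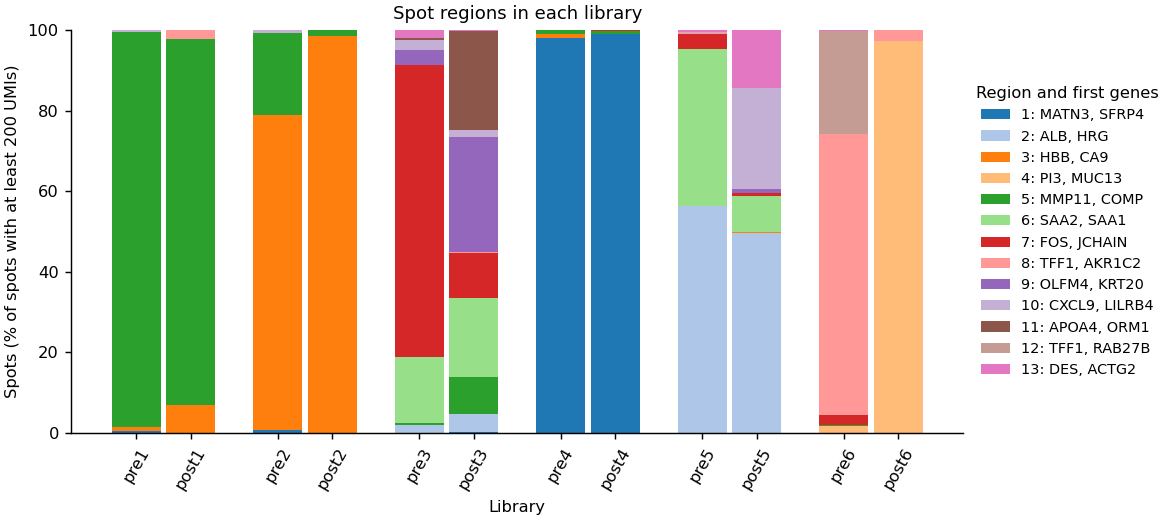
Percent of spots in each of 13 regions per section, pre and post by pair, as stacked bars that sum to 100%. Most regions belong to 1 pair or 1 section, and region 5 is present in 10 of 12 sections.

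The authors' deposited table of spatial autocorrelation gave between 123 and 3028 genes per section with an adjusted p under 0.05 (median 548). Of the genes in the authors' deposited table, 4144 were listed in all 12 sections, 0 of them were patterned in all 12 and 9 in at least 10. By the authors' deposited table MT-CO1 and the nuclear RNA MALAT1 were patterned in 11 sections, and the matrix genes MGP, COL3A1 and COL1A2, the calcium-binding S100A6, and MT-ND4, MT-CO3 and MT-CYB in 10. COL1A1 was patterned in 9 sections with a median I of 0.192 and HLA-DRA in 8 with 0.101, according to the authors' deposited table. The authors' deposited table gave ALB in 6 sections, EPCAM in 5, KRT19 in 4, CXCL9 in 3, and CSF2RA and PDCD1 in 0. By list, the authors' deposited table had 12 of 18 fibroblast and matrix genes, 9 of 13 mitochondrial, 9 of 31 ribosomal, 3 of 9 MHC class II and 0 of 16 T cell genes patterned in at least 6 sections. The number of patterned genes in the authors' deposited table went with depth: across the 12 sections it correlated with log10 total UMIs at Pearson's r = 0.737 (permutation p = 0.012) and Spearman's rho = 0.727 (permutation p = 0.0096), with r = 0.857 without the 2 sections farthest from the median depth, so it was not compared between the groups.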

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

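In this part, the tests of hepatocyte content, of the shallowest library and of depth behind the mitochondrial share, the fibroblast values without pair 5, and the restriction of co-occurrence to sections with at least 5 expected spots were chosen after the results had been seen. A section was marked when its gap to the nearest section of its group, divided by the group's range, exceeded Dixon's critical value of 0.625 for 6 values. Of 102 groups of values 12 were marked, where chance marks about 5.1.

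The lower fibroblast and matrix list post (median log2 fold change −0.84) may reflect the share of stroma in a biopsy or an effect of treatment. The tables argue against hepatocyte content as the whole cause, since it was lower in all 4 pairs in which the hepatocyte list took under 2% of UMIs in both sections, by −1.90 on the log2 scale (SE 0.513, exact sign-flip p = 0.125, the smallest that 4 pairs allow). Within epithelial-rich spots the list's CPM differed by −0.47 on the log2 scale (lower in 5 of 6 pairs, SD of pair differences 1.36, exact permutation p = 0.658, exact sign-flip p = 0.406), against −1.28 in whole sections (SD 1.72) and −1.71 in epithelial-poor spots, and without pair 5, the 1 pair higher post, these were −0.97, −1.91 and −2.40. Less stroma in the post sections cannot be told apart from a lower level within it, since the spread between pairs covers the values and the ratio moved with pair 5. An effect of GM-CSF on fibroblasts stays open and was not tested apart from the biopsy site, which the labels do not give. Nor can it be told apart from the later time and continued pembrolizumab.

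The mitochondrially encoded list took 488490 CPM in the post section of pair 1, against 69642 to 132590 CPM in the other post sections, and its share there of 48.8% of all UMIs stood against 6.96% to 13.3%. The same section had 5644 genes detected, against 13618 to 16208, and its 10 most abundant genes took 50.4% of UMIs, against 9.43% to 21.5%. Without this library the higher list post was gone (adjusted p = 0.737, direction down), which is what 1 damaged or shallow library would give, so no effect of treatment need be assumed. Whether shallow libraries in general carry a larger mitochondrial share cannot be told from 12 sections: Pearson's r with log10 total UMIs was −0.658 (permutation p = 0.0281), Spearman's rho −0.224 (permutation p = 0.487), and r −0.183 (permutation p = 0.608) without the 2 sections farthest from the median depth. A biological rise of mitochondrial RNA in that section stays possible and was not tested.

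Co-occurrence of T cell and macrophage UMIs was marked in the post section of pair 2, with a log2 ratio of −1.23 against −0.09 to 0.34 in the other post sections, from 0 spots with 0.670 expected. Of 2000 shuffles of T cell UMIs among spots within sections 0.3% gave a difference as low as −0.87 and 1.05% one as far from 0. The bound of 5% set for this test beforehand was wrong, since such shuffles hold no spread between patients and no co-occurrence in any section, so counting error cannot be told apart here. Sections with few expected spots, among them the post section of pair 1 with 0 T cell spots and so a ratio fixed at 0, may carry it: over those with at least 5 expected spots the difference was −0.14 (3 pre and 3 post, too few to reach an exact permutation p under 0.1). A looser neighbourhood of the 2 cell types after GM-CSF therefore remains a hypothesis that rests on sections with few shared spots. CD4 in the T cell list, which macrophages also express, limits the measure further.

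The endothelial list measured 71.7 CPM in the post section of pair 2, against 402 to 705 CPM in the other post sections. Spots with T cell UMIs made up 21.6% in the pre section of pair 3, against 1.49% to 7.52% in the other pre sections. Spots with mast cell UMIs made up 3.26% in the post section of pair 4, against 0% to 0.761%, and spots with eosinophil UMIs 0.389% in the pre section of pair 6, against 0% in the rest. The pre section of pair 4 had 9209 genes detected, against 12526 to 14861, and 6.85% of UMIs from ribosomal protein genes, against 3.02% to 4.44%. In the pre section of pair 5 the 10 most abundant genes took 28.7% of UMIs, against 10.1% to 15.6%.

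Other splits of the sections showed how far chance can be excluded. Where the real count is 0, every split reaches it and the test decides nothing. Post against pre chance could not be excluded: of 100 splits of the 12 sections, the real one included, 99 gave at least the real 20 genes at an unadjusted p under 0.05 (highest other 1309) and 87 at least the real 4 lists (highest other 12). For the real 0 genes past the threshold, 100 of 100 decide nothing (highest other 178). A split that calls 178 genes points to a structure of the sections other than time. Among the 32 ways of exchanging pre and post within pairs, all of which part 6 pairs, 23 gave at least 149 genes at such a p (highest other 522) and 31 at least 5 lists (highest other 12), while the 32 that gave at least 0 genes (highest other 30) decide nothing.

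For the contrasts within sections, rich and poor were exchanged within patients in 32 ways. In the macrophage contrast only the real split gave 38 genes (1 of 32, highest other 0) or 546 at an unadjusted p under 0.05 (1 of 32, highest other 431). The 11 lists were reached by 7 of 32 (highest other 12). In the epithelial contrast only the real split gave 595 genes at such a p (1 of 32, highest other 427). The 8 lists were reached by 5 of 32 (highest other 9), and the 0 genes past the threshold decide nothing (32 of 32, highest other 1). A share of 1 in 32 is the smallest these splits allow. Spots were sorted by the list's own RNA, so genes expressed together with it may differ by that choice. Exchanging sorted spots cannot test for that, so chance is not called excluded. For camera's counts of lists, chance could thus be excluded in none of the comparisons put to these splits. The change of the epithelial contrast from pre to post could not be told from chance: 17 of 50 splits gave at least 90 genes at such a p (highest other 216), and within pairs 5 of 32 (highest other 176). For the macrophage contrast these were 47 of 50 for 22 genes (highest other 150), and within pairs 19 of 32 (highest other 58). The real 0 genes past the threshold decide nothing in either: 50 of 50 (highest other 18) and within pairs 32 of 32 (highest other 6) for the epithelial contrast, 50 of 50 (highest other 3) and 32 of 32 (highest other 0) for the macrophage contrast.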

How the results depend on the processing

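Alternatives without pair 6, and blocked ones without a pair, with another tool or with a covariate, were chosen after the data had been seen. Post against pre, 33 of 34 alternatives gave 0 genes, and the patient block without pair 5 gave 8. No list share or spot share passed under any of 21 and 17 alternatives, and the macrophage contrast did not change from pre to post under any of 18. The co-occurrence difference kept its sign and stayed between −1.05 and −0.65 in all 17 alternatives. It lost its call in 2, the patient block (−0.87, exact sign-flip p = 0.0625) and that block without pair 1 (−0.90, exact sign-flip p = 0.125). The patient block also gained the call of the immediate early list and, adjusted over the list alone, that of 1 endothelial and 1 immediate early gene.

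The number of lists called post against pre was 4. It was 0 with an estimated correlation, without or with the patient block, and between 2 (without the pre section of pair 5) and 10 (without the post section of pair 2) when 1 section was left out. In the blocked fit, which called 5, it was 7, 8, 7, 8 and 6 without pair 1, 2, 3, 4 or 5 and 8 without pair 6, the pair imaged at another scale. The cause was not tested.

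Some lists turned direction past or around the threshold. Without pair 1, whose post library is under 50000 UMIs, the mitochondrial list pointed down in the blocked fit (adjusted p = 0.931) and without that library in the unblocked one (0.737). The ribosomal list was called up in both (0.0287 and 0.0467). The blocked fit called the hepatocyte list down without pair 3 (1.14e-10), the type I interferon list up without pair 2 (0.00141), the hypoxia list up without pair 6 (0.00684), and the macrophage list down with the epithelial list as a covariate (0.0263). It called the macrophage list up without pair 1 (0.0287), 2 (0.0477) or 6 (1.81e-04), but not without pair 3, 4 or 5. The GM-CSF signalling list was called down without pair 1 (0.0287), 4 (0.0434), 5 (0.0455) or 6 (0.0348), but not without pair 2 (0.0743) or 3 (0.983). These are camera's adjusted p at the preset correlation. With an estimated one they were 0.428 for the hepatocyte, 0.384 for the type I interferon and 0.410 for the hypoxia list. For the macrophage and GM-CSF signalling calls without a pair they were at least 0.406. Leaving out 1 section, camera's adjusted p ranged from 0.0182 to 0.914 for the macrophage list, 0.0453 to 0.983 for type I interferon, 1.82e-08 to 0.737 for mitochondrial and 0.00102 to 0.983 for ribosomal genes. Over all lists 260 of 403 alternatives kept direction and side of the threshold, 34 gained and 19 lost a call, 13 turned direction and 77 moved without a call. The cause was not tested.

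The epithelial contrast called 0 genes of 4130. It called 130 with a filter at 10 UMIs in all, 119 with DESeq2, 55 in pre sections alone, 1 in post sections alone, 12 in thinned spots, 4 with spots divided at the median, 3 without pair 6, and between 0 and 56 leaving out 1 patient (56 without pair 5). The macrophage contrast called 38. It called 157 with that filter (35 shared), 6 with a division at the median (6 shared), 3 in pre and 6 in post sections alone (3 and 5 shared), 2 in thinned spots (2 shared), 0 without the patient block (2.16% of genes at an unadjusted p under 0.05), and between 0 and 45 leaving out 1 patient. In the macrophage contrast thinned spots left 630 genes to test and sections of 1 time 1333 and 2502. The cause of the different counts was not tested in either contrast. The change of the epithelial contrast called 1 gene with DESeq2 and between 0 and 4 leaving out 1 section (4 without the post section of pair 4).

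Named genes kept direction and side in 1950 of 2221 alternatives post against pre (4 gained a call), 386 of 473 in the epithelial contrast (57 gained) and 401 of 470 in the macrophage contrast (40 lost, 5 gained). Depth limited the tests most in the post section of pair 1 and the pre section of pair 4, with 36805 and 75904 UMIs. Clustering gave 10 regions at resolution 0.3, 19 at 1.0 and 11 from spots with at least 500 UMIs. The authors' deposited table gave a median of 374.5 patterned genes at an adjusted p under 0.01.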

Other observations

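The biology described first here was chosen after the values had been seen. Mast cell RNA was lower post in every pair: the list's summed CPM was 104 ± 110 pre and 40.3 ± 41.1 post (SD, n = 6 each), and the tryptase TPSB2, a granule protease, went from 47.2 to 14.2 CPM, lower in 6 of 6 pairs. The protease CPA3 was lower in 5 pairs (14.5 to 6.47 CPM), and TPSAB1, KIT, MS4A2 and HPGDS were lower in more pairs than higher. Of the 8 members, GATA2 was higher in 4 of 6 pairs (11.7 and 10.3 CPM) and HDC, with 3 UMIs, higher in 1 and lower in 1. Only 310 UMIs stood behind the list, 141 of them of TPSB2. The exact sign-flip p of 0.0312, the smallest that 6 pairs allow, could not pass for 1 list alone over 27 lists (adjusted p = 0.844). Among genes with the smallest p in the blocked fit, the tight junction gene CLDN5 of endothelium measured 56.1 ± 38.5 CPM pre and 13.7 ± 12.6 CPM post (blocked log2 fold change −1.88 ± 0.408 SE, adjusted p = 0.562), and was the 1 endothelial gene to pass adjusted over the list alone. EGR1, an immediate early gene, gave −0.95 ± 0.286 (lower in 6 of 6 pairs) and the lymphoid chemokine CCL19 −1.40 ± 0.489. On the higher side stood the mucin MUC13 (1.31 ± 0.378) and the basal keratin KRT17 (1.41 ± 0.470, higher in 6 of 6 pairs), none past the threshold over all genes (adjusted p = 0.999).

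Without pair 5, the pair whose fibroblast and matrix list was higher post, the blocked fit called 8 genes, all lower: COL3A1 (−2.06 ± 0.385), LTBP2 (−2.08 ± 0.401), COL1A1 (−1.90 ± 0.373), COL1A2 (−1.92 ± 0.404), the proteoglycan BGN (−1.91 ± 0.380), COL14A1 (−1.73 ± 0.360), COL5A1 (−1.73 ± 0.354) and C11orf96 (−1.76 ± 0.361), with adjusted p between 0.0328 and 0.0359. With all 6 pairs the same genes measured −1.53 for COL3A1, −1.36 for COL1A1 and −1.16 for COL14A1 (adjusted p = 0.999). Pair 5 was singled out because of its values, so this count is no independent evidence of a change.

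Region 10, led by CXCL9, which draws activated T cells, lay 89.2% in the post section of pair 5. Its spots held CXCL9 at 352 CPM against 37.1 CPM elsewhere, and more macrophage (log2 1.92), MHC class II (1.82), cytotoxic lymphocyte (1.81), T cell (1.69) and interferon gamma response UMIs (1.33) than other spots. These values describe 232 spots of few sections and were not compared between the groups. Region 13, with the smooth muscle genes DES, ACTG2 and MYH11, lay 92.2% in the same section.

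In macrophage-rich spots further immune genes outside the fixed rule passed: the inhibitory collagen receptor LAIR1 (log2 1.73, adjusted p = 0.0211), the chemokine receptor CXCR4 (1.69, adjusted p = 0.0388), and the leukocyte surface genes CD52 (1.65, adjusted p = 0.0421) and CD53 (1.87, adjusted p = 0.0424). The growth factor receptor EGFR was lower in 6 of 6 patients (−1.0 ± 0.256) without passing (adjusted p = 0.0896). In the other contrast, of epithelial-rich against epithelial-poor spots, ANXA1 and ANTXR1 (1.51) leaned higher post. There the metabolic enzyme IDH2 (−1.86), the protease inhibitor SERPINA1 (−1.32) and the fibrinogen gene FGG (−1.72) leaned lower, none past the threshold.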
